A study of Mus musculus with 25 samples.

How the data were processed

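RNA of 3T3-L1 adipocytes, a mouse cell line that is grown as preadipocytes and differentiated into fat cells in culture, was measured on 25 one-colour Affymetrix arrays. Per the labels, total RNA was isolated with Trizol and hybridised as biotin-labelled cRNA, and the arrays of a group are biological replicates. The labels name a control (LA) and a treatment (CLA) and a time of 4, 8, 12 or 24 h, which gives 8 groups of 2 to 4 arrays. LA and CLA are not spelled out in the labels; in adipocyte work they usually stand for linoleic acid and conjugated linoleic acid. Neither the dose nor the isomer was given in the sources used here.

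The deposited value table gives 1 intensity per probe set and array on a linear scale for 45101 probe sets. The scanner software, the summary method and any scaling by the authors were not given in the sources used here. The values show that a background had been subtracted, since 21.6% of them lie at or below 0, and that the arrays had not been scaled to a common level, since their mean intensities run from 72.6 to 149.2. The authors also deposited 1 table per time with a ratio and an absolute fold change per probe set, the log10 of that ratio with its error, a p-value and 2 scaled intensities. Per the file names these come from Rosetta Resolver, and the arrays of a group were combined in them. The direction of the authors' deposited ratio is not stated and was worked out from the values: their first intensity lay closer to the mean of the LA arrays than to that of the CLA arrays at each of the 4 times, so a ratio above 1 was read as higher under CLA. The second intensity was not used here.

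Probe sets were named through the platform's annotation table: 34958 had 1 gene symbol, 932 had several and 9211 had none. Of the probe sets with 1 symbol, 34754 had an Entrez identifier found in the RefSeq gene table, and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests. Values were floored at 0, an offset of 0.984 (the 25th percentile of all values) was added, and log2 was taken, so that a difference is on the log2(intensity + offset) scale. The arrays were then quantile normalised. A gene was represented by its probe set with the highest mean, and genes were kept when they exceeded the array's median in at least 2 arrays, which left 14428 of 18194 genes. Among named genes past the threshold with at least 2 probe sets (81 combinations of gene and time), 16 had a probe set of the other sign and 0 had one that passed with the other sign. An offset this small stretches differences of dim genes, so several genes are also given with their value under a larger offset of 57.7 (the 75th percentile), most of them near the floor in 1 group. The median difference over all genes lay between -0.06 and 0.01 at the 4 times. For arrays, their number limits the precision.

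The tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) on all 25 arrays with 8 group means, so that the groups share 1 estimate of the spread. Contrasts were CLA minus LA at each time, the difference of these effects between times (a moderated F-test, and 24 h minus 4 h), and change over time in the LA arrays (a moderated F-test). 16 gene lists with 388 entries were tested with limma's camera at a preset correlation of 0.01, all 64 list and time combinations adjusted together, and again with the correlation estimated. limma's fry was run beside it. Its directional p was under 0.05 for every list that camera called in the fit with array sets except cholesterol synthesis and fibroblast markers at 4 h, and fat synthesis, mitochondrial, glycolysis and fibroblast lists at 8 h. It compares no list with other genes. Design, normalization, filter, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named, at each time, the 5 genes with the largest rise and the 5 with the largest fall among those past the threshold whose CLA arrays all lay on 1 side of the LA arrays. It also named 20 key genes and up to 4 members of each list that passed its test, chosen by the smallest p.

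A principal component analysis and clustering of the arrays without use of the treatment showed 5 sets of arrays that the labels do not name. A fit with these sets as a term (called the array-set fit) was chosen after seeing the data. The planned fit has no such term, and counts from both are given. In the array-set fit the 5 largest rises and falls past its threshold were named by another rule, also set after seeing the data: the difference between CLA and LA had to have 1 sign in every array set that holds both. Sets holding both an LA and a CLA array of a time numbered 2 at 4 h (sets B and C), 2 at 8 h (A and B), 4 at 12 h (B, C, D and E) and 3 at 24 h (B, D and E). At 12 and 24 h every array has such a partner, so both fits give the same differences there and only their errors differ. The median standard error of a difference fell from 0.67, 0.60, 0.52 and 0.60 at 4, 8, 12 and 24 h in the planned fit to 0.34, 0.31, 0.26 and 0.30 in the array-set fit.

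Groups share replicate numbers, so it was checked whether arrays with the same number deviate together from their group means. Across genes they correlated at 0.50, 0.16, 0.31 and 0.56 for the 4 pairs at 12 h and at 0.34, 0.27 and 0.28 for the 3 pairs at 24 h, so the numbers were taken to pair the arrays at these times. They were not taken to do so at 4 h (-0.25 and 0.33) and at 8 h (0.31, 0.17 and 0.07). For 8 h this choice is uncertain. Each LA array correlated best with its own number there, and 0.17 lies above the 0.16 of a pair at 12 h. No 2 arrays held identical values; the highest correlation of deposited values between any 2 was 0.996.

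Both fits were tested on simulated data built on the 14428 genes, with 100 genes changed at each of 2 sizes. The simulated arrays were made from each gene's array-set means and the residual spread of the array-set fit. A higher recovery by that fit thus follows from how the data were made and does not favour it over the planned fit. For CLA minus LA, the planned fit recovered 2, 3, 5 and 0% of the genes changed by 1 log2 unit at 4, 8, 12 and 24 h and 18, 22, 29 and 22% of those changed by 2 units. The array-set fit recovered 35, 40, 45 and 40% at 1 unit and 59, 60, 64 and 61% at 2 units. For the F-test of the difference between times, the planned fit recovered 0% at either size and the array-set fit 28% and 53%. Alternatives were the deposited values without normalization, median centring, no offset, a median offset (9.75) and the larger offset. Further ones were no filter and a filter at the 75th percentile, the mean of a gene's probe sets, all probe sets and only the groups compared. The rest were an intensity trend, array weights, the replicate block, 4 array sets, the fit without set C, and each array left out in turn. The larger offset, the array-set term, 4 sets and the fit without set C were chosen after seeing the data.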

Results

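Transcript levels were measured in cultured 3T3-L1 mouse adipocytes that received LA as the control or CLA as the treatment, and the design asks which genes differ between the treatments at 4, 8, 12 and 24 h. There were 3 LA and 2 CLA arrays at 4 h, 3 and 3 at 8 h, 4 and 4 at 12 h, and 3 and 3 at 24 h. Each time had its own LA arrays. Mean intensities of the arrays ran from 72.6 to 149.2, and 72.4% to 80.7% of the probe sets on an array were above 0. Differences are log2 CLA minus LA with their standard errors. Genes are said to have risen or fallen where the adjusted p of limma was under 0.05 in the array-set fit, and lists to have shifted where that of camera was.

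The treatment accounted for 2.33% of the first principal component, which held 28.7% of the variance, and for 21.0% of the second, which held 10%. Clustering gave 5 sets of arrays that the labels do not name. They accounted for 96.8% of the first component, but they were made from the same values, so a large share follows from how they were made. Set B held the 8 arrays numbered replicate 2, a number that the clustering did not use, and set C held 5 dim arrays with 75th percentiles of intensity of 26.5 to 37.5, against 54.5 to 85.0 in sets B, D and E. In set A they ran from 29.7 to 68.3, and LA 4 h replicate 1, at 29.7, was as dim as set C. The actin 3′ to 5′ ratio, a measure of RNA integrity, was 8.11 in LA 4 h replicate 1 and 5.67 in LA 12 h replicate 1, against 1.43 to 3.32 in the other 23 arrays.

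**Figure D1:**
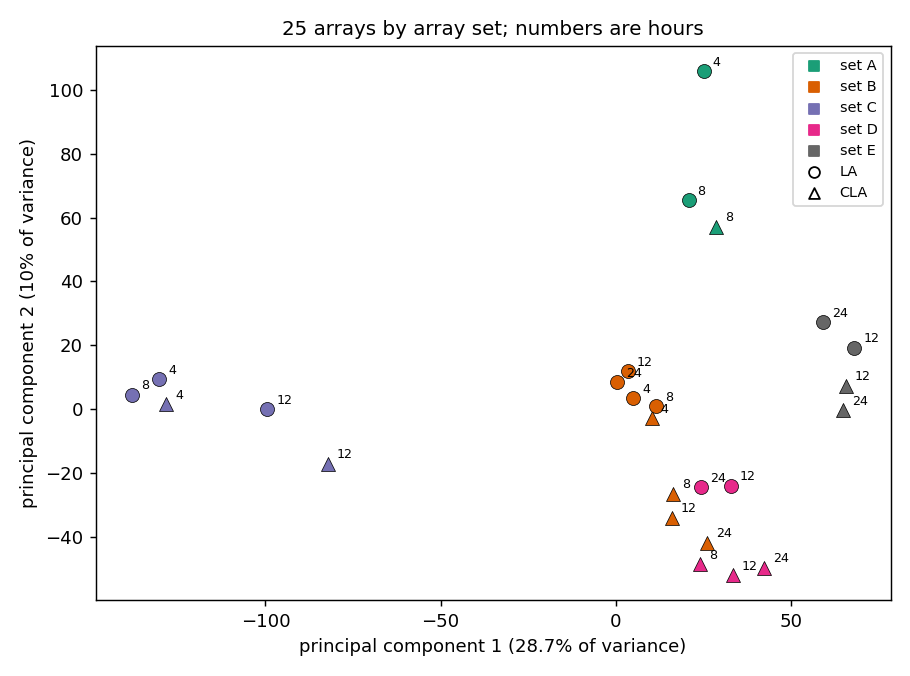
Each point is 1 of the 25 arrays, placed by its scores on the first and second principal components of the log2 values (28.7% of the variance on the first), with circles for LA, triangles for CLA, numbers for the hours and colours for the 5 array sets. Set C lies at the low end and set E at the high end of the first component, and sets A, B and D overlap on it.

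At 4 h the immediate early genes, transcription factors and signalling regulators that respond fast to stimuli, lay above the LA level as a list, with a median difference of 1.15 over 19 measured members (2 CLA and 3 LA arrays), a call that was lost with an estimated correlation (adjusted p = 0.073). Targets of ATF4, the transcription factor of the integrated stress response, shifted up with a median of 0.22 over 44 members (adjusted p = 0.13 with an estimated correlation). Targets of NRF2, which governs antioxidant genes, shifted up with 0.17 over 19 members, and cholesterol synthesis genes with 0.29 over 20 (adjusted p = 0.13 and 0.35 with an estimated correlation). In the planned fit the cholesterol synthesis median had the other sign, at -0.07 (camera adjusted p = 0.883). Fibroblast and preadipocyte markers shifted down with -0.26 over 20 members (adjusted p = 0.48 with an estimated correlation). Etv5, an ETS transcription factor, rose by 1.53 ± 0.22 (adjusted p = 0.0341), and by 0.60 with the larger offset. The transcripts 4930431P19Rik (-3.91 ± 0.41, adjusted p = 0.0017) and AU015836 (-3.83 ± 0.56, adjusted p = 0.0341) fell to the floor of the scale in both CLA arrays. Both were dim in LA, and with the larger offset their differences were -0.33 and -0.37 and did not pass. Other probe sets of Etv5 and 4930431P19Rik reached -1.73 and 2.19, against the sign given. Of the immediate early genes, Egr1 differed by 2.54 ± 0.52 (adjusted p = 0.154) and Jun by 2.54 ± 0.56 (adjusted p = 0.19). The stress-response transcription factors Atf3 and Atf4 differed by 3.27 ± 0.78 (adjusted p = 0.228) and 0.74 ± 0.16 (adjusted p = 0.172). None of these 4 passed the test. With the larger offset, chosen after seeing the data, all 4 passed and Atf3 differed by 2.02.

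The camera adjusted p at 4 h was 6.58e-10 for immediate early genes, 0.000215 for ATF4 targets, 0.00319 for NRF2 targets, 0.00538 for cholesterol synthesis and 0.00942 for fibroblast markers. Adjusted over the list alone, 6 immediate early, 6 ATF4, 4 NRF2 and 1 cholesterol synthesis genes rose, and 1 insulin signalling gene fell. Over all genes tested 0 did so in each list. Of the first 4 lists, 12, 9, 7 and 3 members were higher at an unadjusted p under 0.05 in limma. The median immediate early difference was 0.37 and 1.57 within the 2 array sets that hold both treatments. The planned fit called the immediate early list (adjusted p = 2.97e-12, and 0.029 with an estimated correlation) and the ATF4 list (adjusted p = 0.000183, and 0.5 with an estimated correlation). The array-set fit called 3 genes at 4 h, 1 higher and 2 lower, and the planned fit 1, which was 4930431P19Rik. Without CLA replicate 2, which leaves 1 CLA array that is assumed to vary like the other groups, the array-set count was 241, and without CLA replicate 1 it was 3. Without LA replicate 2 it was 31.

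At 8 h the lists of immediate early genes, NRF2 targets, ATF4 targets and inflammatory genes lay above the LA level (3 CLA and 3 LA arrays), also with an estimated correlation (adjusted p = 0.038, 0.017, 0.042 and 0.042). In the planned fit the first held with it (adjusted p = 0.0096) and the other 3 were lost (adjusted p = 0.58, 0.58 and 0.081). Ptgs2, which encodes the prostaglandin synthase COX-2, rose by 4.72 ± 0.37 (adjusted p = 4.22e-05). Atf3 rose by 4.77 ± 0.70 (adjusted p = 0.00509), and the EGF receptor ligand Ereg by 4.28 ± 0.76 (adjusted p = 0.0114). Hmox1, which encodes heme oxygenase 1, rose by 2.59 ± 0.34 (adjusted p = 0.00229), and Srxn1, which encodes sulfiredoxin, by 2.52 ± 0.30 (adjusted p = 0.000809). Slc2a4, the insulin-responsive glucose transporter GLUT4, fell by 1.62 ± 0.32 (adjusted p = 0.0232), and Cebpa, a transcription factor of adipocyte differentiation, fell by 0.99 ± 0.21 (adjusted p = 0.0306).

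Of 19 measured immediate early genes 9 rose, among them Ier3 (3.25 ± 0.48), Egr1 (3.05 ± 0.47) and Jun (2.46 ± 0.50), and the list had a median of 2.17. Of 19 NRF2 targets 7 rose, with a list median of 0.59; beside Hmox1 and Srxn1 they included Txnrd1, thioredoxin reductase (1.25 ± 0.19). Of 44 ATF4 targets 9 rose, with a median of 0.32, including the aminoacyl-tRNA ligases Iars (0.72 ± 0.15) and Nars (0.76 ± 0.17), the amino acid transporter Slc7a1 (1.22 ± 0.24) and asparagine synthetase Asns (0.49 ± 0.11). Of 26 inflammatory genes 4 rose, with a median of 0.75, among them Socs3, a feedback inhibitor of cytokine signalling (1.56 ± 0.28), and the chemokine Cxcl1 (3.40 ± 0.69). Il6 (2.46 ± 0.89, adjusted p = 0.186) and Ccl2 (1.43 ± 0.52, adjusted p = 0.191) did not pass. They differed by 0.58 and 0.86 with the larger offset, and Il6 then passed. Of 20 cholesterol synthesis genes 4 rose, with a median of 0.50. In the other direction 3 of 22 adipocyte genes fell (median -0.40) and 3 of 23 genes of fatty acid and triglyceride synthesis (median -0.25). The latter included the phosphatidate phosphatase Lpin1 (-1.23 ± 0.28) and the lipogenic transcription factor Srebf1 (-0.77 ± 0.18). Fasn, fatty acid synthase, differed by -0.97 ± 0.28 (adjusted p = 0.0923) and did not pass.

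The camera adjusted p at the preset correlation was 1.17e-18 for immediate early genes, 1.14e-09 for NRF2 targets, 1.59e-08 for ATF4 targets and 6.58e-10 for inflammatory genes at 8 h. The other 7 calls were lost with an estimated correlation, among them cholesterol synthesis (4.32e-07, then adjusted p = 0.12 with an estimated correlation), adipocyte genes (0.00127, then 0.28) and fatty acid and triglyceride synthesis (0.0119, then 0.51). Also lost were mitochondrial genes of the TCA cycle and oxidative phosphorylation (median -0.12, 0.0119, then 0.55), glycolysis (median -0.23, 0.025, then 0.48), insulin signalling (median -0.26, 0.0354, then 0.30) and fibroblast markers (median 0.28, 0.00293, then 0.43). The planned fit did not call cholesterol synthesis, glycolysis or insulin signalling at 8 h (camera adjusted p = 0.312, 0.187 and 0.791). It called cell cycle (median 0.63, 0.000996) and fatty acid oxidation (median -0.42, 0.00215), which were lost there with an estimated correlation (0.58 and 0.51). The array-set fit called neither of these 2 lists (camera adjusted p = 0.349 and 0.127). Adjusted over the list alone, 17 immediate early, 9 NRF2, 13 ATF4, 6 inflammatory and 8 cholesterol synthesis genes rose, and 6 adipocyte and 6 fat synthesis genes fell. Against these directions, 2 ATF4 and 1 cholesterol synthesis genes fell and 1 adipocyte gene rose. Hspa5, an endoplasmic reticulum chaperone, rose by 0.75 ± 0.17 (adjusted p = 0.0413), alone among 23 measured chaperone and unfolded protein response genes, a list with an adjusted p of 0.962. Another probe set of Hspa5 reached -0.19, against the sign given.

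The array-set fit called 261 genes at 8 h, 180 higher and 81 lower, and the planned fit 4. Of the array-set calls 69% were higher, against 97% with the values as deposited and 89% with each array centred on its median. The planned calls were Dusp5, a phosphatase of ERK kinases (6.70 ± 1.01, adjusted p = 0.0162), Ereg (4.31 ± 0.71, adjusted p = 0.0328) and Ifrd1 (2.24 ± 0.34, adjusted p = 0.0162), which were higher, while a lower value was found for Hdhd3 (-1.81 ± 0.31, adjusted p = 0.0478). Dusp5 was at the floor in all LA arrays of 8 h, and its array-set difference of 6.94 ± 0.95 was 1.61 with the larger offset. With that offset Ptgs2 differed by 1.12, Atf3 by 2.78, Ereg by 2.58 and Hdhd3 by -1.02. Other large differences at 8 h were those of dim transcripts. Dnmt3l rose by 3.62 ± 0.80, and Unc5a (-3.61 ± 0.82), 3110070M22Rik (-3.49 ± 0.79), Gm17546 (-3.31 ± 0.57), Kcna4 (-2.72 ± 0.64) and Rab27b (-2.45 ± 0.49) fell. With the larger offset these 6 differed by 0.37, -0.25, -0.22, -0.19, -0.17 and -0.28, and Rab27b alone of them passed. Other probe sets of Kcna4 and Rab27b reached 0.32 and 0.21. LA and CLA replicate 3 of 8 h lie in different array sets, and leaving out any 1 of the 6 arrays of 8 h lowered the count to between 23 and 166.

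At 12 h NRF2 and ATF4 targets lay above the LA level and adipocyte genes below it, also with an estimated correlation in the array-set fit (4 CLA and 4 LA arrays), while these 3 calls were lost with it in the planned fit (adjusted p = 0.24, 0.42 and 0.24). Immediate early and inflammatory genes lay above it and fat synthesis below it in calls that were lost with an estimated correlation (adjusted p = 0.054, 0.11 and 0.13), though the immediate early call held in the planned fit (adjusted p = 0.0096). Atf3 rose by 5.01 ± 0.58 (adjusted p = 0.000986) and Ptgs2 by 4.35 ± 0.31 (adjusted p = 1.04e-05). Ereg rose by 4.22 ± 0.63 (adjusted p = 0.0033) and Srxn1 by 2.27 ± 0.25 (adjusted p = 0.000549). Each was higher in 4 of 4 array sets. Thrsp, a regulator of lipogenesis, differed by -2.78 ± 0.29 (adjusted p = 0.000549), and Fasn by -1.62 ± 0.23 (adjusted p = 0.00256). Slc2a4 differed by -1.81 ± 0.27 (adjusted p = 0.00327) and Cebpa by -1.43 ± 0.18 (adjusted p = 0.00101). Each was lower in 4 of 4 sets. Pparg, the nuclear receptor that governs adipocyte differentiation, differed by -0.54 ± 0.14 (adjusted p = 0.0401).

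Of 22 adipocyte genes 10 fell and 1, Angptl4, rose (1.27), with a list median of -0.60. The falls included the transcription factor Klf15 (-3.40 ± 0.76) and Gpd1, glycerol-3-phosphate dehydrogenase (-1.51 ± 0.33). Of 23 genes of fatty acid and triglyceride synthesis 7 fell, with a median of -0.52, including Lpin1 (-1.64 ± 0.23) and the carbohydrate-responsive transcription factor Mlxipl (-3.05 ± 0.74). Of 23 mitochondrial genes 3 fell (median -0.24), among them the cytochrome oxidase subunits Cox7a1 (-1.37 ± 0.33) and Cox5a (-0.40 ± 0.10). Of 16 glucose uptake and glycolysis genes 3 fell, including Pfkfb3 (-1.54 ± 0.26), and the glucose transporter Slc2a1 rose (1.16 ± 0.29), with a median of -0.20. Of 16 insulin signalling genes 3 fell, namely Tbc1d4, Pde3b and Pik3r1 (median -0.28). Of 25 fatty acid oxidation genes 1, Hadh, fell (-0.38 ± 0.10; median -0.25). Of lists with rising members, 9 of 19 immediate early genes (median 1.37), 9 of 19 NRF2 targets (median 0.67), 10 of 44 ATF4 targets (median 0.35), 3 of 26 inflammatory genes (median 0.66) and 2 of 20 cholesterol synthesis genes (median 0.27) rose.

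Adjusted over the list alone, 12 immediate early, 12 NRF2, 17 ATF4, 6 inflammatory and 3 cholesterol synthesis genes rose at 12 h. In the same way 15 adipocyte, 11 fat synthesis, 7 mitochondrial, 5 fatty acid oxidation, 5 insulin signalling and 4 glycolysis genes fell. Against these directions, 2 NRF2, 1 ATF4 and 1 cholesterol synthesis genes fell, and 1 adipocyte, 1 fatty acid oxidation and 1 glycolysis genes rose. Camera called 11 lists: immediate early (adjusted p = 1.03e-11), adipocyte (6.21e-11), NRF2 (2.9e-09), fat synthesis (1.59e-08), mitochondrial (1.59e-08), ATF4 (2.44e-08), inflammatory (3.09e-06), insulin signalling (0.000922), glycolysis (0.00251), fatty acid oxidation (0.00293) and cholesterol synthesis (0.00383). With an estimated correlation the NRF2 (adjusted p = 0.017), ATF4 (adjusted p = 0.042) and adipocyte (adjusted p = 0.046) calls held. The others did not, with an adjusted p of 0.054 for immediate early genes, 0.11 for inflammatory genes, 0.13 for fat synthesis and for insulin signalling, 0.15 for mitochondrial genes, 0.30 for fatty acid oxidation and 0.33 for glycolysis and for cholesterol synthesis.

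The array-set fit called 677 genes at 12 h, 331 higher and 346 lower, and the planned fit 4. All 4 were higher, namely Ereg (adjusted p = 0.0184), Dusp5 (adjusted p = 0.0316), Ier3 (adjusted p = 0.0316) and Ifrd1 (adjusted p = 0.0323). With the replicate number as a block 6 genes passed, 0 of these 4 among them (adjusted p = 0.124 for Ereg, Dusp5 and Ier3 and 0.073 for Ifrd1). Dusp5 differed by 5.34 ± 0.79 and by 1.26 with the larger offset, and with it Klf15 differed by -1.30, Mlxipl by -0.69, Cox7a1 by -0.65, Pfkfb3 by -0.86, Atf3 by 2.50, Ereg by 2.28 and Ptgs2 by 1.02. Dim Plet1 rose by 3.65 ± 0.87. The co-receptor gene Klb (-3.30 ± 0.84), Rph3al (-3.24 ± 0.73), Morn1 (-3.15 ± 0.72) and Cxcr6 (-3.15 ± 0.77) fell. These 5 had 0.53, -1.13, -0.22, -0.23 and -0.27 under the larger offset, where Rph3al did not pass. Other probe sets went against the sign given for Plet1 (to -1.15), Rph3al (to 1.52), Morn1 (to 1.68) and Cxcr6 (to 1.31). Of the list members, those of Gpd1 (to 2.50) and Thrsp (to 0.46) did so too. Leaving out LA replicate 1 or CLA replicate 1 gave 884 and 854 genes, and leaving out any other array of 12 h gave 163 to 372. Without the 5 arrays of set C the count was 96.

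At 24 h mitochondrial genes had the most falling members of the 16 lists. Of the 23 measured genes of the TCA cycle and oxidative phosphorylation 20 fell and none rose, with a median of -0.60 (3 CLA and 3 LA arrays). Among them Sdhb, a subunit of succinate dehydrogenase, differed by -1.06 ± 0.16 (adjusted p = 0.00203), and Idh3a, a subunit of isocitrate dehydrogenase, by -0.92 ± 0.18 (adjusted p = 0.01). Cox7a1 differed by -2.45 ± 0.38 (adjusted p = 0.00242). Of 23 fat synthesis genes 11 fell, in a list call that was lost with an estimated correlation (adjusted p = 0.073). Among the 11 were Thrsp at -4.69 ± 0.33 (adjusted p = 1.04e-05) and Fasn at -2.01 ± 0.27 (adjusted p = 0.000863). Another probe set of Thrsp reached 0.58, against the sign given. The triglyceride synthesis enzyme Dgat2 was at -1.96 ± 0.31 (adjusted p = 0.00243) and stearoyl-CoA desaturase Scd1 at -1.16 ± 0.23 (adjusted p = 0.01). Slc2a4 differed by -2.55 ± 0.31 (adjusted p = 0.000478) and the lipid droplet gene Cidec by -2.20 ± 0.29 (adjusted p = 0.000791). Pparg differed by -0.88 ± 0.16 (adjusted p = 0.00723) and the adiponectin gene Adipoq by -0.78 ± 0.17 (adjusted p = 0.0168). Each of these genes was lower in 3 of 3 array sets.

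Of 22 adipocyte genes 12 fell and Angptl4 rose (1.27), with a list median of -1.24, and the median of fat synthesis genes was -0.84. Of 25 fatty acid oxidation genes 10 fell, among them Echs1 (-1.18 ± 0.17), Decr1 (-1.11 ± 0.19) and Acadm (-0.75 ± 0.18), with a list median of -0.74. In this list Cpt1a, the carnitine palmitoyltransferase that controls entry of fatty acids into mitochondria, rose (0.93 ± 0.22, adjusted p = 0.0248). Of 16 glucose uptake and glycolysis genes 5 fell, including Pfkfb3 (-2.41 ± 0.30) and hexokinase 2, Hk2 (-1.29 ± 0.23), with a median of -0.44. Of 16 insulin signalling genes 1, the phosphodiesterase Pde3b, fell (-2.62 ± 0.42; median -0.40). Fabp4, the adipocyte fatty acid binding protein, differed by -0.08 ± 0.10 (adjusted p = 0.798). It was the brightest gene on 15 of the 25 arrays and lay at the highest value of the normalised scale on 9. A rise could not show on those 9, and a fall only where its rank dropped. The authors' deposited table gives a ratio of 0.92 for it at 24 h, with a p of 0.506. The 4 probe sets of Fabp4 differed by -0.22 to 0.11 at 24 h, so no fall was seen by either measure.

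Of lists with rising members at 24 h, 6 of 19 NRF2 targets rose and 1, Taldo1, fell (median 0.65), with Srxn1 at 1.90 ± 0.28, Nqo1 at 0.87 ± 0.20 and Hmox1 at 0.97 ± 0.33 (adjusted p = 0.119). Of 44 ATF4 targets 6 rose and 1 fell (median 0.18), with Atf3 at 3.79 ± 0.67 and Shmt2, mitochondrial serine hydroxymethyltransferase, at 1.04 ± 0.15. Of 26 inflammatory genes 3 rose (median 0.71): Ptgs2 (2.88 ± 0.36), the chemokine Ccl5 (3.48 ± 0.80) and Socs3 (1.16 ± 0.27). Of 19 immediate early genes 1, Ier3, rose (1.70 ± 0.46; median 0.90). Of 25 cell cycle genes none passed, with a median of 0.85, of -0.22 to 1.89 within the 3 array sets, and 13 members higher at an unadjusted p under 0.05 in limma. Fibroblast and preadipocyte markers also had 0 of 20 members past the threshold over all genes and 0 adjusted over the list alone, with a median of 0.35 and 6 members higher at an unadjusted p under 0.05. Macrophage markers (median -0.06, mean 0.23) had a camera adjusted p of 0.337 at 24 h and of 0.31, 0.70 and 0.404 at 4, 8 and 12 h. Of them Cd14 rose at 8 and 12 h (2.41 and 1.42, and 1.22 and 0.68 with the larger offset).

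Adjusted over the list alone, 22 mitochondrial, 17 fat synthesis, 16 fatty acid oxidation, 15 adipocyte, 9 glycolysis and 7 insulin signalling genes fell at 24 h. By the same adjustment 14 ATF4, 9 NRF2, 6 cell cycle, 5 immediate early and 3 inflammatory genes rose. Against these directions, 2 NRF2 and 1 ATF4 genes fell, and 2 fatty acid oxidation, 1 adipocyte and 1 glycolysis genes rose. Camera called 12 lists at 24 h. With an estimated correlation 3 of them held, namely mitochondrial genes (adjusted p = 1.54e-22, and 0.042 with an estimated correlation), adipocyte genes (1.07e-13, and 0.042) and NRF2 targets (6.49e-06, and 0.042). In the planned fit 0 of the 12 held with it, and these 3 had an adjusted p of 0.14, 0.11 and 0.42. The calls that were lost had, with an estimated correlation, an adjusted p of 0.073 for fat synthesis (9.57e-13 before) and for fatty acid oxidation (1.19e-08), and 0.082 for inflammatory genes (4.74e-07). It was 0.13 for glycolysis (5.97e-07), 0.14 for cell cycle (9.65e-09), ATF4 targets (0.000453) and insulin signalling (0.00295), 0.15 for immediate early genes (8.04e-06) and 0.28 for fibroblast markers (7.28e-05). The medians within the 3 array sets ran from -1.32 to -0.75 for adipocyte genes, from -1.03 to -0.42 for fatty acid oxidation and from -0.72 to -0.42 for mitochondrial genes, and those for fat synthesis were at or below -0.41.

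The array-set fit called 664 genes at 24 h, 127 higher and 537 lower. The planned fit in limma called 0, with 566 genes at an unadjusted p under 0.05 where chance gives 721.4, and the fit with the replicate number as a block called 23. The planned fit has no term for the pairs of arrays at 24 h, so variation that a pair shares enlarges the errors of that fit. A count below chance thus does not show that CLA had no effect. The largest falls past the threshold were those of Apoc4 (-6.11 ± 0.58), Klf15 (-5.21 ± 0.88), Mlxipl (-4.96 ± 0.86), the lipid droplet lipase Pnpla3 (-4.75 ± 0.74) and Thrsp. The largest rises were those of Dusp5 (3.97 ± 0.91), Atf3, Lce1g (3.56 ± 0.95), Ccl5 and the collagenase Mmp13 (3.33 ± 0.73). With the larger offset Apoc4 differed by -1.14, Klf15 by -2.10, Mlxipl by -0.75, Pnpla3 by -1.98, Thrsp by -3.78, Dusp5 by 0.66, Lce1g by 0.44, Ccl5 by 0.45 and Mmp13 by 1.24. Further, Atf3 differed by 1.73, Cox7a1 by -1.09, Pfkfb3 by -1.08, Ier3 by 1.11, Nqo1 by 0.43 and Ptgs2 by 0.66 with it, and Dusp5 and Ptgs2 did not pass. Leaving out CLA replicate 1 gave 624 genes, and leaving out any other array of 24 h gave 188 to 396.

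**Figure D2:**
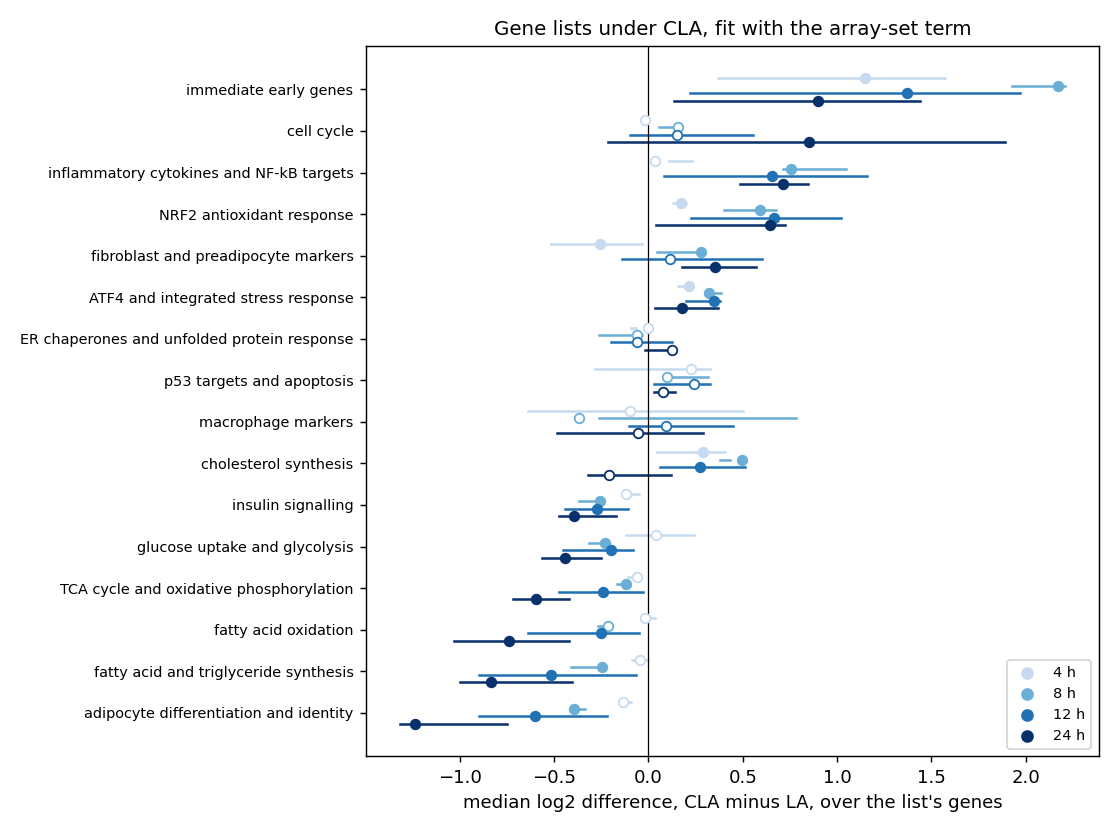
Points give the median log2 difference, CLA minus LA, of each of the 16 gene lists at 4, 8, 12 and 24 h in the array-set fit, filled where camera's adjusted p at the preset correlation was under 0.05, and lines span the lowest and highest median within an array set. Mitochondrial genes reach -0.60 and adipocyte genes -1.24 at 24 h, and the median of immediate early genes is 2.17 at 8 h and 0.90 at 24 h.

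Calls at different times overlapped by more than independent lists would. At both 8 and 12 h 119 genes rose and 54 fell, where independent lists of those sizes would share 4.13 and 1.94. At both 12 and 24 h 71 genes rose, of 331 at 12 h, and 205 fell, of 346, where independent lists would share 2.91 and 12.9. At 8 and 24 h the shared calls were 36 and 45, and 1 gene went in opposite directions. At all of 8, 12 and 24 h 35 genes rose and 39 fell. The 537 genes lower at 24 h, chosen at that time, had median differences of -0.06, -0.42, -0.52 and -0.90 at 4, 8, 12 and 24 h. The calls at different times are not independent in that fit. All times share 1 estimate of the spread of a gene, so a gene with a small spread can pass more easily at several times. At 4 and 8 h the array-set effects, which are shared between times, also enter the differences. The expected numbers take no account of this.

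The CLA effect itself differed between times for 2 genes in the array-set fit, Thrsp (adjusted p = 0.0214) and Ptgs2 (adjusted p = 0.01). Thrsp differed from LA by -0.40, -1.50, -2.78 and -4.69 at 4, 8, 12 and 24 h, and Ptgs2 by -0.34, 4.72, 4.35 and 2.88. Thrsp passed this test with the larger offset too, and Ptgs2 did not (adjusted p = 0.012 and 0.237). Between 24 and 4 h the effect differed for 21 genes, 3 with a higher and 18 with a lower value at 24 h. This count was 0 with the values as deposited, the mean of probe sets, without set C or with 4 array sets, and leaving out 1 array moved it to between 1 and 199. The count of 2 was 0 under the last 3 of these 4 settings. Among the 18 was Slc2a4 (a difference of -2.60 ± 0.47, adjusted p = 0.0495). Chosen after their values were seen, others were the apolipoprotein genes Apoc4 (-5.81 ± 0.89, adjusted p = 0.0238) and Apoc3 (-3.53 ± 0.60, adjusted p = 0.0336). Further ones were the seipin gene Bscl2 (-1.79 ± 0.27, adjusted p = 0.0238) and Uqcrfs1 of respiratory complex III (-1.19 ± 0.22, adjusted p = 0.049). With the larger offset these 5 differed between 24 and 4 h by -1.75, -0.94, -1.42, -1.33 and -1.15 in that order, and all 5 passed. As lists, mitochondrial genes (adjusted p = 4.79e-13), fat synthesis (3.7e-09) and adipocyte genes (8.09e-08) were lower at 24 h than at 4 h, with an adjusted p of 0.22 for each with an estimated correlation. Immediate early genes were lower at 24 h than at 8 h (1.93e-07, and adjusted p = 0.22 with an estimated correlation). The planned fit in limma called 0 genes in both tests, with 323 and 418 at an unadjusted p under 0.05.

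**Figure D3:**
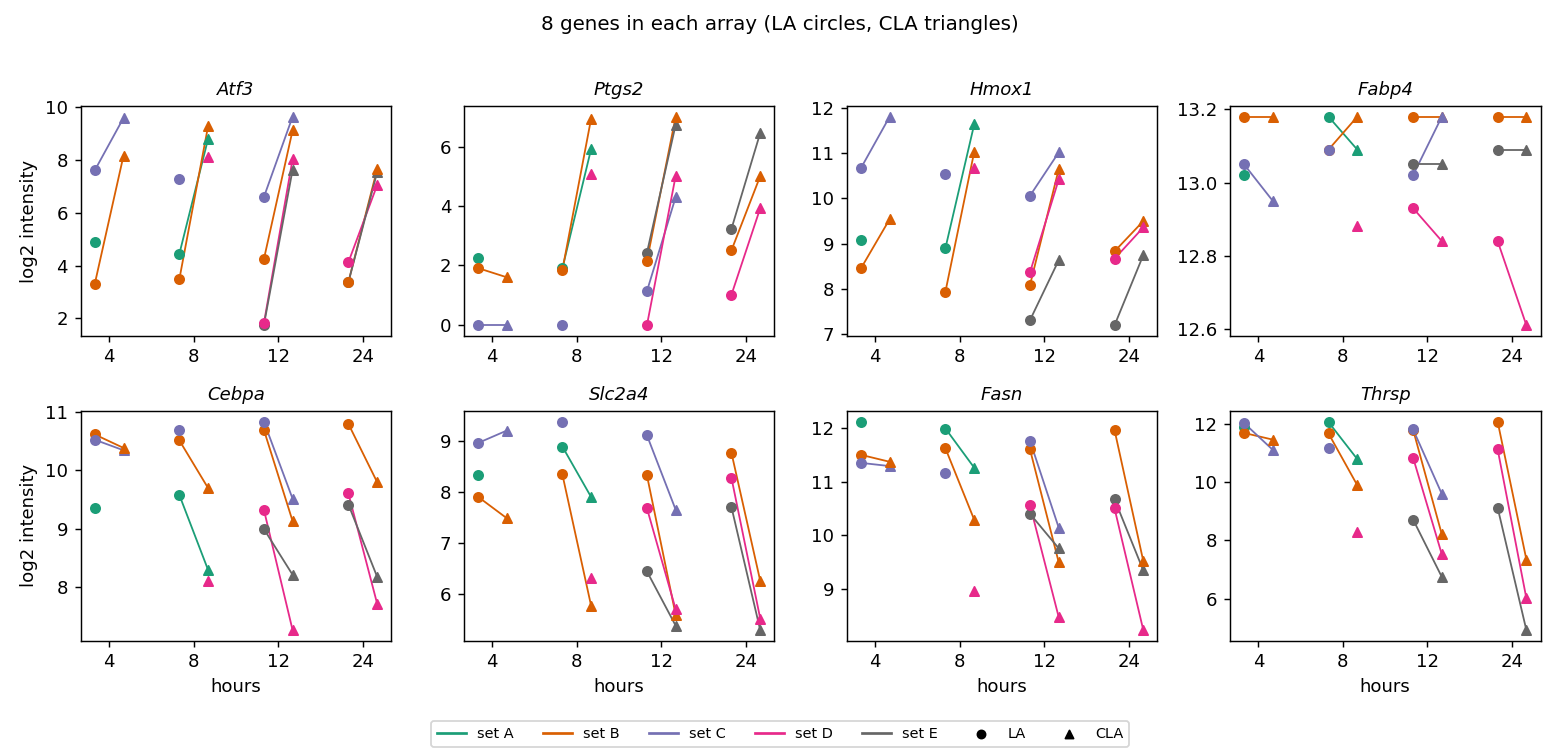
Log2 intensities of Atf3, Ptgs2, Hmox1, Fabp4, Cebpa, Slc2a4, Fasn and Thrsp on each array are plotted against the time in hours, and lines join the LA and CLA arrays of 1 array set and time. Thrsp lies lower under CLA in 4 of 4 sets at 12 h and in 3 of 3 at 24 h, and Ptgs2 lies higher in as many.

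In the LA arrays alone, 0 genes passed for change over the 4 times in limma's F-test in either fit. At an unadjusted p under 0.05 there were 485 genes in the planned fit and 1277 in the array-set fit, where chance gives 721.4. In the simulated data this test recovered 1% and 29% of genes changed by 1 and 2 log2 units in the planned fit. In the array-set fit it recovered 32% and 72%. A count of 0 thus does not show that levels were stable. Mean log2 levels of Fasn in LA were 11.66 ± 0.41 (SD, n = 3), 11.59 ± 0.41 (SD, n = 3), 11.08 ± 0.70 (SD, n = 4) and 11.04 ± 0.80 (SD, n = 3) at 4, 8, 12 and 24 h. Those of Cebpa were 10.16 ± 0.70, 10.26 ± 0.60, 9.96 ± 0.94 and 9.94 ± 0.75.

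The authors' deposited tables list 84, 717, 428 and 552 probe sets with a p under 0.01 at 4, 8, 12 and 24 h, and 7, 129, 50 and 71 after Benjamini-Hochberg adjustment at 0.05. Chance alone would put a share of 0.01 of the 45101 probe sets under 0.01 at each time. The counts under 0.01 at 4 and 12 h lie below that share, and those at 8 and 24 h above it. Of the 552 at 24 h, the authors' deposited table gives 414 as lower under CLA, and of the 717 at 8 h the authors' deposited table gives 415 as higher. Among the genes tested here, the authors' deposited tables put 50, 438, 268 and 366 under 0.01. Each of these had the same sign in the array-set fit, which called 0, 142, 199 and 267 of them. The authors' ratios and this fit rest on the same arrays, from which the direction of the ratio was also read. The shared sign is thus not independent support. The authors' deposited ratios of Adipoq were 0.80, 0.71, 0.69 and 0.56 at the 4 times. Log2 ratios of the authors' deposited tables correlated with the planned differences across genes, which are not independent replicates, at 0.67, 0.74, 0.76 and 0.80, and with those of the array-set fit at 0.55, 0.66, 0.76 and 0.80.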

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

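Tests chosen only after the result was seen were the array-set fit itself and, at 24 h, those of adipocyte share, of RNA quality and of the lists within array sets. The tests on the small count at 4 h were prompted by the counts with 1 array left out, and the comparison of its 2 pairs with later effects was added after the correlation between them was seen.

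Effects of CLA that differed between times stood out in the array-set fit. The F-test over the 4 times called 2 genes and the contrast of 24 h with 4 h called 21. Among the named genes, the effect at 24 h minus that at 4 h was -5.81 for Apoc4, -4.29 for Thrsp, -2.60 for Slc2a4, 3.22 for Ptgs2 and 3.64 for 4930431P19Rik. With the larger offset these 5 were -0.94, -3.39, -1.75, 0.69 and 0.28, and the last 2 did not pass (adjusted p = 0.304 and 0.28). Shifts of gene lists differed between times for 8 lists between 8 and 4 h, 8 between 12 and 4 h and 9 between 24 and 4 h. They did so for 10 between 24 and 8 h and 9 between 24 and 12 h. With an estimated correlation in camera 0 lists differed in each comparison.

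Probe sets that the annotation ties to no single gene were not part of the gene tests, and 10, 16, 62 and 52 of 10092 passed the threshold at 4, 8, 12 and 24 h in the array-set fit over all probe sets.

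Single arrays stood far from the rest of their group in 13 of 134 groups of 4 values at 12 h, where chance alone gives about 1 in 20. The groups are values of the same arrays and not independent, so that share is only a rough guide. At 12 h each treatment has 1 array in each of sets B, C, D and E, so a set that lies apart can appear as a single array. Each value that follows in brackets is the gap to the nearest array over the range of the group. LA replicate 1 of 12 h had an actin 3′ to 5′ ratio of 5.67 against 1.49 to 1.73 in the other LA arrays (0.942) and a Gapdh ratio of 1.42 against 0.84 to 0.88 (0.94). The same array was apart for Dusp5, at 4.22 against the floor in the others (1, as for any gap to arrays tied at the floor), for Ereg at 5.51 against 3.26 to 3.62 (0.838) and for Hk2 at 8.84 against 9.54 to 9.66 (0.861). CLA replicate 1 of 12 h, of the same array set, was apart for the Gapdh ratio (0.848) and for Slc2a1 at 8.38 against 9.92 to 10.12 (0.883). For Rph3al its value was 0.03 with the others tied at the floor, a small gap that gives 1 whatever its size. CLA replicate 4, of the dim set C, was apart for Pik3r1 at 6.80 against 8.27 to 8.51 (0.858), Slc2a4 at 7.65 against 5.39 to 5.71 (0.859) and Srebf1 at 8.42 against 7.02 to 7.26 (0.831). LA replicate 4, also of set C, had 75.3% of its probe sets above 0 against 79.8% to 80.6% (0.842), and LA replicate 2 had Il6 at 0.13 against 3.18 to 3.42 (0.926).

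The array-set fit called many more genes than the planned fit, 261 against 4 at 8 h, 677 against 4 at 12 h and 664 against 0 at 24 h. If the genes with the smallest p were false calls, they should go either way in a pair of arrays left out of the fit. Of the 200 genes with the smallest p, a median of 94% went the same way in the left-out pair. The range was 90.0% to 98.0% over 9 pairs. This speaks to those 200 genes alone, since the weaker calls that the added term gained were not scored. The array sets had been formed with the left-out pair included. The planned fit was not scored in this way, so the 94% does not tell the fits apart. Whether the added term made false calls among the weaker genes stays open. Of 10 splits at 8 h, and of 8 and 4 that part each pair at 12 and 24 h, the real one included, those that do not follow the treatment called at most 1, 1 and 0 genes (1 among all 35 at 12 h and 1 among all 10 at 24 h). These splits are too few for a share under 0.05, and 1, the real one, reached its count. What the array sets are (cultures, days or hybridisations) stays open, since no label names them.

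Far fewer genes passed at 4 h than at 12 h in the array-set fit, 3 against 677. The smaller number of arrays argues little: with 12 h reduced to 5 arrays in 2 ways, 319 and 560 genes were still called. Effects in the 2 pairs of 4 h, of sets B and C, correlated across genes at 0.0368, below the 0.0544 to 0.197 between pairs at the other times, which cannot tell whether 1 of the pairs deviates or which. Against the mean later effect in sets A, D and E, the pair of set B correlated at 0.0757 and that of set C at 0.0372, so set B is not singled out. Without CLA replicate 2, of set B, 241 genes were called, but that fit rests on 1 CLA array, and the other fit with 1 CLA array, without replicate 1, called 3. A deviating pair and a smaller effect of CLA at 4 h both stay open.

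At 24 h the adipocyte, fat synthesis, fatty acid oxidation and mitochondrial lists were lower under CLA, and the fat synthesis and fatty acid oxidation calls were lost with an estimated correlation (adjusted p = 0.073 for each), as were all 4 in the planned fit (adjusted p = 0.11, 0.15, 0.26 and 0.14). RNA quality is argued against by the actin ratio of CLA over LA, which was 0.939, 0.969 and 0.985 in the 3 array sets. Each of these sets holds 1 LA and 1 CLA array of 24 h, so a shift shared by a set cancels from the differences by design. List medians lay below 0 in 12 of 12 combinations of list and set, so the falls did not come from 1 set alone. A lower share of adipocytes stays open, since fibroblast and preadipocyte markers lay above LA in 20 of 20 members (median 0.35, and 0.18 to 0.57 within the 3 array sets; camera adjusted p = 7.28e-05, and 0.28 with an estimated correlation). Adipocyte members (n = 18) below the brightest 1% of genes did not fall by an equal amount (Cochran's Q = 260, p = 1.5e-45 with errors taken as independent, and Q = 392 with the larger offset), but genes that the other cells also express would fall less, so this does not exclude a change in share. A response of these adipocytes to CLA was not tested apart from such a change and stays open too, and the 4 splits at 24 h are too few to judge chance.

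Other splits were also counted for the remaining results. In the planned fit 4 genes were called at 8 h and at 12 h, where other splits gave at most 1 and 0 (2 among all 35 at 12 h), and 0 at 24 h, where all 4 splits gave 0 (1 at most among all 10). For gene lists in the planned fit the real counts were 10, 10 and 12 at 8, 12 and 24 h against at most 9, 10 and 9 in other splits, and in the array-set fit 11, 11 and 12 against 7, 13 and 9. Among all 35 splits at 12 h and all 10 at 24 h, other splits gave at most 11 and 9 lists in the planned fit and 13 and 11 in the array-set fit. At 12 h 2 of 8 splits in the planned fit and 3 of 8 in the array-set fit, the real one included in each, gave at least as many list calls as the real one (5 and 7 among all 35). Camera with its preset correlation thus called as many lists there in some other splits. In the array-set fit each of those splits exchanged 1 LA and 1 CLA array, so part of a CLA effect remains in them. Splits with 2 LA arrays on each side that part each pair gave 3, 5 and 9 lists in that fit. In the planned fit they gave 0, 2 and 7, and a split of this balance that kept pairs together gave 10. The splits thus cannot give the rate of false list calls. The 10 splits at 8 h, and those that part each pair at 12 and 24 h, are too few for a share under 0.05. For change over time in the LA arrays 0 genes were called, a count that each of the 100 drawn assignments reaches by construction in both fits, so the comparison says nothing about chance. In the planned fit 1 assignment called 3488 genes, and in the array-set fit the most was 4. The array sets were made from the same values, so a drop in such calls follows from how they were made. Whether that assignment lines up with the sets was not tested.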

How the results depend on the processing

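The array-set fit, its 4-set version, the larger offset, the fit without set C and all alternatives of the array-set fit were chosen after seeing the data. The others were planned. No list call reversed direction under any alternative of either fit, and of the named genes' values 0 that were past the threshold changed sign. Of all 4751 values under the alternatives in the planned fit and 4305 in the array-set fit, 77 and 61 changed sign. Named genes kept their side of the threshold in 4504 and 3584 of all these values, crossed it upward in 161 and 139 and lost the call in 86 and 582. The cause of the moves was not tested except where fewer arrays or genes entered by construction. Dim signal is 1 limit: 21.6% of values lie at or below 0, and counts at 8, 12 and 24 h in the array-set fit grew with the offset.

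In the planned fit, counts of genes at 4, 8, 12 and 24 h were 1, 4, 4 and 0, and of lists 2, 10, 10 and 12. At 4 h 2 genes passed with no filter and 4 with all probe sets. None (0) passed with the values as deposited, median centring, no offset, a median offset, the stricter filter or the mean of probe sets. Nor did any with only the groups compared, the intensity trend, array weights, the 75th-percentile offset or without set C. At 8 h the count moved to 8 with deposited values, 0 with all probe sets, 1 with only the groups compared, 52 with array weights and 7 with the 75th-percentile offset. At 12 h it moved to 1 with all probe sets, 1 with only the groups compared, 35 with array weights, 2 with the 75th-percentile offset and 1 without set C. At 24 h it moved to 1 with deposited values, 4 with the stricter filter, 1 with only the groups compared, 5 with the intensity trend and 34 with array weights. It was 3 with the 75th-percentile offset and 2 without set C. With the array-set term the counts were 3, 261, 677 and 664. Lists at 4 h moved to 6 with array weights, 5 with the array-set term and 4 without set C, and with the estimated correlation lists numbered 1, 1, 1 and 0. Without a filter 1 gene each passed for the difference between times, for 24 h minus 4 h and for LA over time. Array weights gave 4 and the fit without set C 3 for LA over time, and the array-set term 2 and 21 for the differences.

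With the replicate block 5, 1, 6 and 23 genes passed at 4, 8, 12 and 24 h (2 higher and 21 lower at 24 h), with 5 lists at 4 h, and the pairing changed no other count of lists or differences by as much. At 12 h 0 of the 4 planned calls were among the 6. At 4 h the numbers do not pair the arrays, since LA replicate 3 correlates best with CLA replicate 1 (0.454). At 8 h the pairing is uncertain. Each LA array correlates best with its own number there, but LA replicate 3 hardly so (0.067, against 0.063 with CLA replicate 2). The block could not be fitted to LA over time, where a block lies within a time.

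In the array-set fit, deposited values gave 59, 72 and 93 genes at 8, 12 and 24 h and median centring 162, 328 and 415. Of those at 8 h 97% and 89% were higher, against 69% with quantile normalization. For the other settings the counts that moved, at 8, 12 and 24 h, were 584, 1158 and 1101 with the stricter filter, 548, 1070 and 1030 with the intensity trend, 770, 1281 and 1293 with the 75th-percentile offset and 76, 162 and 225 with 4 array sets. The mean of probe sets gave 129 and 405 at 8 and 12 h, array weights 552 and 1209 at 8 and 24 h, and the fit without set C 104 and 96 at 8 and 12 h. At 4 h the count was 0 with the median offset, the mean of probe sets or without set C and 1 with the trend, array weights or 4 sets. It was 5 with no filter, 11 with all probe sets and 14 with the 75th-percentile offset. Estimated correlations left 0, 4, 3 and 3 lists. Genes whose effect differs between times numbered 1 with deposited values, the median offset or all probe sets, 5 with no filter, 16 with the stricter filter, 40 with the trend and 36 with the 75th-percentile offset. They numbered 0 with the mean of probe sets, without set C or with 4 sets. For 24 h minus 4 h they numbered 0 with deposited values, the mean of probe sets, without set C or with 4 sets, 11 with no offset and 32 with the median offset. They numbered 86 with the stricter filter, 148 with the trend, 2 with array weights and 136 with the 75th-percentile offset. LA over time gave 2 without set C.

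Leaving out each array in turn, the planned counts ran from 1 to 81 at 4 h (81 without CLA replicate 2, which leaves 1 CLA array assumed to vary like the other groups, and 13 without LA replicate 2 of 4 h), 0 to 5 at 8 h, 0 to 7 at 12 h and 0 to 1 at 24 h. Lists ran from 2 to 6 at 4 h, 8 to 10 at 8 h, 8 to 11 at 12 h and 10 to 13 at 24 h. Differences between times ran from 0 to 3, 24 h minus 4 h from 0 to 10 and LA over time from 0 to 14, the highest without LA replicate 2 of 4 h. In the array-set fit the counts ran from 1 to 241 at 4 h, 23 to 308 at 8 h, 163 to 884 at 12 h and 188 to 680 at 24 h. Lists ran from 2 to 6, 7 to 12, 11 to 12 and 12 to 13. Differences between times ran from 1 to 89, 24 h minus 4 h from 1 to 199 and LA over time from 0 to 32. The highest counts for both kinds of difference came without CLA replicate 2 of 4 h, and for LA over time without LA replicate 2 of 4 h. At 8 h the count fell to 55, 99 and 95 without LA replicates 1, 2 and 3 and to 57, 23 and 166 without CLA replicates 1, 2 and 3. At 12 h it fell to 177, 316 and 187 without LA replicates 2, 3 and 4 and to 163, 278 and 372 without CLA replicates 2, 3 and 4. At 24 h it fell to 396, 202 and 357 without LA replicates 1, 2 and 3 and to 188 and 310 without CLA replicates 2 and 3.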

Other observations

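The list and gene tests were planned, but the values in this part come from the array-set fit, which was chosen after seeing the data. No other test in this part was planned, and the genes named here were chosen after their values were seen. Targets of p53, the transcription factor of the DNA damage response, did not shift as a list (camera adjusted p = 0.0903, 0.051, 0.321 and 0.532 at 4, 8, 12 and 24 h). Even so, 3 of 12 measured members rose at 8 h in the array-set fit, namely the stress sensor Gadd45a (1.81), the cell cycle inhibitor Cdkn1a (0.84) and the p53 ligase Mdm2 (0.64). Gadd45a rose again at 12 h (1.49, and 0.95 with the larger offset). Genes of the unfolded protein response did not shift at any time (camera adjusted p = 0.56, 0.962, 0.736 and 0.461), while ATF4 targets shifted up at each of the 4 times, in calls lost with an estimated correlation at 4 h (adjusted p = 0.13) and 24 h (adjusted p = 0.14). Cholesterol synthesis genes, which shifted up at 4, 8 and 12 h in calls lost with an estimated correlation (adjusted p = 0.35, 0.12 and 0.33), had a median of -0.21 at 24 h (adjusted p = 0.0903). The planned fit did not call this list at 4, 8 or 12 h (camera adjusted p = 0.883, 0.312 and 0.165). In the array-set fit the difference between the effects on these genes at 24 and 8 h had a median of -0.65 (adjusted p = 1.3e-10, and 0.22 with an estimated correlation).

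The 2 main glucose transporters of adipocytes moved in opposite directions. Slc2a1, the basal transporter GLUT1, rose at 8 h (1.90) and 12 h (1.16), while Slc2a4 fell at 8, 12 and 24 h (-1.62, -1.81 and -2.55). Within the fatty acid oxidation list Cpt1a rose at 24 h (0.93) while Ehhadh (-2.68) and Hadhb (-0.82) fell; with the larger offset Ehhadh differed by -0.34 and did not pass. In the mitochondrial list Cox8b had the lowest value at 24 h (-3.53, and -0.77 with the larger offset), and in the adipocyte list Klf15 (-5.21, and -2.10 with it).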
